A study of Mus musculus with 8 samples.

How the data were processed

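RNA was measured in colon tissue from 8 Rag1-knockout mice of the C57BL/6 strain, 5 given regulatory T cells (Treg-injected controls) and 3 given naïve T cells and killed with severe colitis. Mice lacking Rag1 make no mature T or B cells, so their T cells come from the transfer, and innate cells, NK cells among them, are their own. Per the labels' protocols, mice were injected at 10 weeks of age and killed 2 to 4 months later. The labels give ages of 4 to 5 months, which does not match these times in full, so the ages at death are uncertain. The labels call the replicates biological, and each array was taken as a separate mouse. The sources used here give different sampled regions: the sample protocol names distal colon and the series design a strip along the whole colon, so the region is uncertain.

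Biotin-labelled targets were prepared with an Affymetrix whole-transcript kit, per the labels' protocols, and hybridised to Affymetrix arrays whose model is not given in the sources used here. The deposited values are log2 intensities per probe set, made by the authors with Affymetrix Expression Console and RMA (background correction, normalization between arrays and summary over probes), per the submitters' processing notes. Versions and settings are not given in the sources used here, and the log2 scale was taken from the range of the values. Array medians over transcript clusters lay between 4.81 and 4.91, so the arrays had been brought to a near-common scale. RMA compresses low signals, so folds of genes near background are understated. Precision is limited by the number of arrays, since the files give no counts and no detection calls.

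The table held 72688 probe sets, of which 65956 were transcript clusters and the rest controls, left out of every test. Gene symbols came from the array's annotation, updated through the RefSeq gene table of GRCm38.p6 for 1137 symbols. Of the 32750 annotated probe sets, 30604 had 1 symbol, 622 had several symbols of 1 gene, and 1524 with several genes were left unnamed. A further 33206 transcript clusters had no symbol. The 31226 named probe sets covered 30671 genes, and for the 440 genes with over 1 probe set the one with the highest mean was used. No positions are given, because the files name no genome build.

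Log2 values were compared between groups, inflamed minus control, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate, no intensity trend). Genes with a Benjamini-Hochberg adjusted p under 0.05 are said to have risen or fallen, and a second count required at least a 2-fold change. Fold changes are differences of log2 means with their limma standard error (SE) after ±, with n = 5 control and 3 inflamed arrays throughout. Group means carry the standard deviation (SD).

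For 41 gene lists holding 868 genes, 779 of them measured, each member's call was counted, both over all genes and adjusted over the list alone. The 39 lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation. The lists, the tests, the groups and the alternatives were fixed before the data were examined, except where said otherwise. Named genes followed a rule fixed at the same time. It took the 10 largest rises and 10 largest falls past the threshold with non-overlapping groups, clone names, small RNAs and receptor segments aside. It also took, per list, the 3 members past the threshold with the largest changes (or the 2 largest of any, if under 2 passed), and the p21-activated kinases and sex-linked genes. Pak1, Ddx3y, Lck, Foxp3 and Cd74 were among the list genes with no named probe set and are not analysed here.

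An exact two-sided permutation test of list means was added after the data were seen. The mean log2 value over a list's members was taken per array, and the difference of group means was set against all 56 splits of the 8 arrays into 5 and 3, with Benjamini-Hochberg adjustment over the 41 lists. Its smallest p is 0.0179, or 0.0261 after adjustment, and it is reached only when the 3 inflamed arrays all lie on the same side of the control range. Genes of a list move together, and this test, unlike camera with a preset correlation, allows for that. It does not set a list against other genes.

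The scripts were tested on simulated data with the spread of these 30671 genes. Of 100 genes changed by 1 log2 unit, 83% were recovered, and of 100 changed by 2 units 97%, with 15 false calls. All 20 simulated lists shifted by 0.5 were recovered and 0 of 20 unshifted lists were called, in a simulation with independent genes. The changed genes and the list genes were drawn only from genes brighter than the array median, so these rates do not cover dimmer genes.

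Alternatives covered other scalings, a floor on low values, leaving out dim genes, the mean over a gene's probe sets, every probe set, an intensity trend with robust variances, array weights, the replicate number as a block, each array left out in turn, a threshold of 0.01, and fry in place of camera. A block for sex, as Xist and Y-linked genes show it, and leaving out genes with under 5 distinct values were added after the data were seen. Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were also used.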

Results

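Transfer of naïve T cells into mice without mature T and B cells is a model of inflammatory bowel disease, in which the cells expand and drive colitis, while transferred regulatory T cells do not. Expression was measured in the colons of 5 mice given regulatory T cells and 3 mice with severe inflammation after naïve T cells, with 1 array per mouse. The comparison addresses which transcripts differ between severely inflamed and control colon, and the series title names signalling by p21-activated kinases.

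Control arrays resembled each other more than they resembled inflamed arrays, as did inflamed replicates 1 and 3, while inflamed replicate 2 stood apart. Across 65956 transcript clusters, Pearson's r was 0.994 to 0.997 for pairs of controls, 0.986 to 0.995 for pairs of inflamed arrays and 0.98 to 0.986 between the groups. Inflamed replicate 2 was at 0.987 and 0.986 with inflamed replicates 1 and 3, close to the highest value between groups. The first principal component of the gene values (62.4% of the variance) separated the groups, with controls from -28.8 to -19.1 and inflamed arrays from 34.8 to 44.1. On the second (17.4%), inflamed replicate 2 lay at 37.0 and the other arrays between -19.0 and 12.7. Exonic control probe sets were separated from intronic ones with an area under the curve of 0.8775 on inflamed replicate 2 and of 0.8829 to 0.8984 on the others.

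The sexes were mixed within both groups. Xist, the RNA that silences the inactive X chromosome of females, was at 10.65 to 11.28 on controls 3, 4 and 5 and inflamed replicate 3, and at 4.11 to 4.53 on controls 1 and 2 and inflamed replicates 1 and 2, which carried the Y-linked transcripts instead. With this pattern as a block, 3269 genes passed the threshold. Within the arrays with Y-linked transcripts alone (2 against 2) 0 genes passed limma's test, with 4591 at an unadjusted p under 0.05, and the other arrays held only 1 inflamed mouse.

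Severe colitis went with a broad change of the colon transcriptome, with calprotectin genes and Cxcl9 among the largest rises and Mptx1 and Hao2 among the largest falls. S100a8, a calprotectin subunit of neutrophils and monocytes, was at 3.72 ± 0.42 in controls (SD, n = 5) and 10.29 ± 1.18 in inflamed colon (SD, n = 3), a rise of 6.57 ± 0.50 on the log2 scale (adjusted p = 0.000533). Its partner S100a9 rose by 5.14 ± 0.59 (adjusted p = 0.00222). Cxcl9, a chemokine induced by interferon-gamma, went from 5.69 ± 0.79 to 11.22 ± 0.39, a 46.2-fold rise of 5.53 ± 0.45 (adjusted p = 0.000633). The mucosal pentraxin gene Mptx1 went from 11.29 ± 1.66 to 5.37 ± 1.85, and fell by 5.92 ± 1.14 (adjusted p = 0.0159).

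The other largest rises were those of Nos2, the inducible nitric oxide synthase, by 4.33 ± 0.45 (adjusted p = 0.0015), and Ido1, which degrades tryptophan, by 4.33 ± 0.50 (adjusted p = 0.00224). The cytokine gene Il1b rose by 4.04 ± 0.44 (adjusted p = 0.00187), the interferon-inducible GTPase gene Iigp1 rose by 3.83 ± 0.61 (adjusted p = 0.00737) and Ubd, a ubiquitin-like modifier, rose by 3.79 ± 0.41 (adjusted p = 0.00171). Ly6c2, a marker of inflammatory monocytes, rose by 3.71 ± 0.21 (adjusted p = 0.000189), and the related surface protein gene Ly6d rose by 3.67 ± 0.26 (adjusted p = 0.000414). Among the falls, Hao2, a peroxisomal hydroxyacid oxidase, went from 10.36 ± 0.30 to 5.05 ± 1.46, and fell by 5.31 ± 0.58 (adjusted p = 0.00183). The sulfotransferase genes Sult1a1 and Sult1c2 fell by 4.24 ± 0.69 (adjusted p = 0.00813) and by 3.65 ± 0.46 (adjusted p = 0.00308). Sucrase-isomaltase (Sis) fell by 3.65 ± 0.39 (adjusted p = 0.00168), syncollin (Sycn) fell by 4.36 ± 0.41 (adjusted p = 0.00105), and the esterase gene Aadac fell by 3.44 ± 0.23 (adjusted p = 0.000337). Mptx2 fell by 5.22 ± 0.98 (adjusted p = 0.0143), the peptidase gene Naaladl1 fell by 3.15 ± 0.33 (adjusted p = 0.0015), and the matricellular protein gene Ccn3 fell by 3.14 ± 0.37 (adjusted p = 0.00236). Sizes and ranks of changes against a level under the dim limit of 4.88 are uncertain. That held for the control means of S100a8, S100a9 and Ubd, and for Mptx1, Mptx2, Hao2, Sult1c2, Sis and Aadac on inflamed replicates 1 and 3. Of the genes named for the lists, a group mean of Ifng, Cxcr6, Havcr2, Mzb1, Stfa2l1, Chil3, Cd80, Mcpt1, Mcpt2, Il1f9, Il1a, Cxcl2, Rgs13, Gnat3, Mmp10, Mmp13 and Tlr13 lay under it too. Intronic control probe sets had array medians of 4.92 to 5.11, so background may reach past that limit. Genes at about that level are uncertain too, among them Cd3g (4.91), Cxcl5 (5.05), Cd3e (5.13) and Il1b (5.18) in controls. Hao2 (5.05) and Ighm (5.12) lay there in inflamed colon. Mptx1 and Mptx2 are near paralogs whose probes may share signal. The Mptx1 call ended without inflamed replicate 1 or 3 (adjusted p = 0.0522 to 0.065) and that of Mptx2 without inflamed replicate 1 (adjusted p = 0.0593).

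In all, 4025 of 30671 genes changed (13.1%), 2477 higher and 1548 lower in inflamed colon, against 8743 genes at an unadjusted p under 0.05. Of the 4025, 730 changed at least 2-fold, 456 upward and 274 downward. For 3976 of the 4025 genes the 3 inflamed values all lay outside the range of the 5 controls. That held for 21.2% of all genes, where chance gives 3.57%. Of 19596 genes above the array median in either group 3829 changed, and of 11075 dimmer genes 196. Without inflamed replicate 1 the count was 2507.

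**Figure D1:**
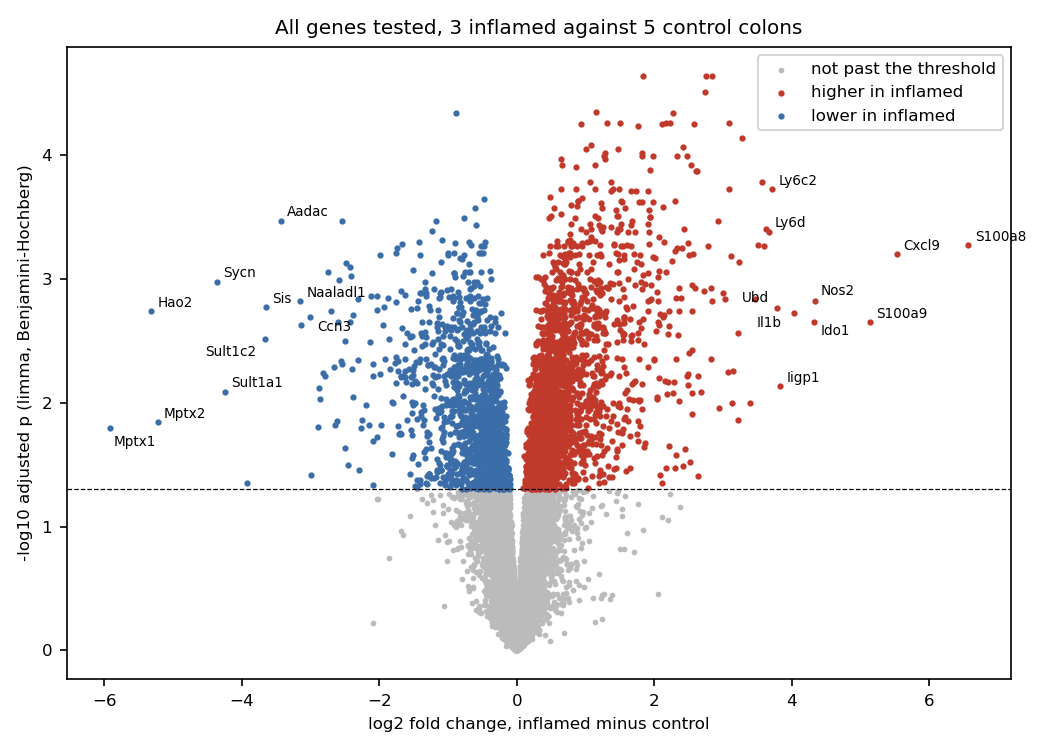
Each point is a gene; the horizontal axis is the log2 fold change (inflamed minus control), the vertical axis the -log10 adjusted p from limma, and the dashed line marks 0.05. Of 30671 genes, 2477 lie higher and 1548 lower past the line, and the 20 largest changes selected by the fixed rule are named, from Mptx1 (-5.92) to S100a8 (6.57).

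Of 39 gene lists tested with camera, 31 passed, 20 upward and 11 downward. With an estimated correlation the complement list alone passed. The exact permutation of list means, which allows for genes moving together, called 31 of 41 lists, 21 upward and 10 downward, of which 28 reached its smallest adjusted p of 0.0261. At that value all 3 inflamed means of a list lay outside the range of the 5 control means.

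Most genes of the T cell list were higher in inflamed colon, as were some genes of an effector list. In the T cell list 13 of the 16 measured members rose and 0 fell, or 15 and 0 adjusted over the list alone, and the list mean was 1.11 log2 units higher. The T cell list had camera adjusted p = 1.33e-11, adjusted p = 0.126 with an estimated correlation and exact permutation adjusted p = 0.0261. Il7r, the survival receptor of naïve and memory T cells, rose by 2.54 ± 0.24 (adjusted p = 0.00112), and the receptor chains Cd3e and Cd3g rose by 2.07 ± 0.18 (adjusted p = 0.000869) and by 1.99 ± 0.27 (adjusted p = 0.00445). Of the Th1 and Th17 effector list, 7 of the 18 measured members rose and 0 fell, or 10 and 0 adjusted over the list alone. The effector list had camera adjusted p = 2.33e-06, adjusted p = 0.0976 with an estimated correlation and exact permutation adjusted p = 0.0261. Tnf rose by 2.31 ± 0.23 (adjusted p = 0.00142), Ifng, the interferon-gamma gene, rose by 2.01 ± 0.17 (adjusted p = 0.000683), and Cxcr6, a homing receptor of effector T cells, rose by 1.91 ± 0.13 (adjusted p = 0.000359). In the list of regulatory T cells and inhibitory receptors, 5 of the 15 measured members rose and 0 fell, or 7 and 0 adjusted over the list alone. The regulatory list had camera adjusted p = 4.81e-05, adjusted p = 0.0976 with an estimated correlation and exact permutation adjusted p = 0.0261. Its leading members were Havcr2, an inhibitory receptor also found on myeloid cells, which rose by 1.16 ± 0.14 (adjusted p = 0.0025), the actin-capping gene Capg, by 0.81 ± 0.089 (adjusted p = 0.00186), and Entpd1, an ectonucleotidase, by 0.76 ± 0.11 (adjusted p = 0.00556). The other 10 measured members did not pass, and Foxp3 had no named probe set. Whole-tissue values do not show which cells carried the transcripts of these lists, so more regulatory T cells are not shown.

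Cytotoxic granule genes were higher as well. In the list of NK cells and cytotoxic granules 7 of the 15 measured members rose and 0 fell, or 7 and 1 adjusted over the list alone. The cytotoxic list had camera adjusted p = 0.000949, adjusted p = 0.142 with an estimated correlation and exact permutation adjusted p = 0.0261. The chemokine Ccl5 rose by 3.03 ± 0.31 (adjusted p = 0.00144), and the granzymes Gzma and Gzmb rose by 2.68 ± 0.43 (adjusted p = 0.00823) and by 2.48 ± 0.37 (adjusted p = 0.00604). Among B and plasma cell genes 1 of the 13 measured members fell and 0 rose, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.0505, adjusted p = 0.344 with an estimated correlation, exact permutation adjusted p = 0.0261), with a list mean difference of -0.0629. Ighm, the IgM heavy chain gene, fell by 0.17 ± 0.041 (adjusted p = 0.0335), and Mzb1, a plasma cell gene, differed by -0.17 ± 0.11 (adjusted p = 0.34). Rag1-knockout mice make no mature B cells. The control and inflamed means of Ighm (5.29 and 5.12) and Mzb1 (5.00 and 4.82) lay near the intronic control medians of 4.92 to 5.11. These small differences may therefore be background and do not show a loss of B cells. The Ighm call ended without control 1, 3, 4 or 5 or inflamed replicate 1 or 3 (adjusted p = 0.0601 to 0.0859), under other scalings and with sex as a block. The count of fallen members was 0 without control 1, 3, 4 or 5 or inflamed replicate 1. Without inflamed replicate 2 the list mean difference was -0.0384 and that of Mzb1 -0.0587. Camera called the list in 5 alternative settings, among them without control 3 (adjusted p = 0.0439), control 4 (adjusted p = 0.0414) or inflamed replicate 3 (adjusted p = 0.0183).

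Neutrophil and macrophage genes were higher in inflamed colon. Of the neutrophil list, 9 of the 22 measured members rose and 0 fell, or 13 and 0 adjusted over the list alone, and its mean was 1.71 higher. The neutrophil list had camera adjusted p = 3.18e-09, adjusted p = 0.222 with an estimated correlation and exact permutation adjusted p = 0.0261. It was led by S100a8 and S100a9, with the values above, and by Stfa2l1, a stefin, which rose by 2.52 ± 0.58 (adjusted p = 0.0301). The 3 inflamed arrays differed, with neutrophil list means of 1.07, 1.35 and 2.70 above control on replicates 1, 2 and 3, and without replicate 3 the mean was 1.21, under that of the interferon-gamma list (1.56). Among monocyte and macrophage genes, 19 of the 23 measured members rose and 0 fell, or 20 and 0 adjusted over the list alone, with a mean 1.57 higher. The macrophage list had camera adjusted p = 2.6e-17, adjusted p = 0.0976 with an estimated correlation and exact permutation adjusted p = 0.0261. Beside Nos2 and Ly6c2, the chitinase-like gene Chil3 rose by 3.24 ± 0.28 (adjusted p = 0.000726). Without inflamed replicate 3, 14 neutrophil genes passed, and the Stfa2l1 call ended without any 1 of the 5 controls or inflamed replicate 2 (adjusted p = 0.0536 to 0.0726).

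In the dendritic cell list 6 of the 16 measured members rose and 0 fell, or 6 and 1 adjusted over the list alone. The dendritic cell list had camera adjusted p = 0.0149, adjusted p = 0.207 with an estimated correlation and exact permutation adjusted p = 0.0261. Sirpa, an inhibitory receptor of myeloid cells, rose by 1.18 ± 0.078 (adjusted p = 0.000321), the integrin gene Itgax rose by 1.08 ± 0.15 (adjusted p = 0.00455) and the costimulator Cd80 rose by 1.003 ± 0.10 (adjusted p = 0.0013). The mast cell protease genes Mcpt1 and Mcpt2 rose while the receptor gene Kit fell. In the list of mast cells and eosinophils 4 of the 16 measured members rose and 1 fell, or 4 and 1 adjusted over the list alone. The mast cell list had camera adjusted p = 0.0545, adjusted p = 0.252 with an estimated correlation and exact permutation adjusted p = 0.0261. Mcpt1 and Mcpt2, proteases of mucosal mast cells, rose by 2.82 ± 0.39 (adjusted p = 0.00441) and by 1.79 ± 0.30 (adjusted p = 0.00951), and Kit, which also marks the pacemaker cells of gut muscle, fell by 1.39 ± 0.17 (adjusted p = 0.00272). With dim genes left out, camera no longer called the dendritic list (adjusted p = 0.22), and other scalings, a trend, array weights or leaving out inflamed replicate 2 (adjusted p = 0.00734) or 3 (adjusted p = 0.043) brought the mast cell list past the threshold.

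The interferon lists moved in opposite directions. Genes induced by interferon-gamma, with those of MHC class I presentation, were higher, while antiviral genes typical of type I interferon were lower. Of the former, 19 of the 24 measured members rose and 0 fell, or 21 and 0 adjusted over the list alone, and the list mean was 1.58 higher. The interferon-gamma list had camera adjusted p = 1.34e-14, adjusted p = 0.152 with an estimated correlation and exact permutation adjusted p = 0.0261. Cxcl9, Ido1 and Iigp1 led it. Of the type I interferon list, 12 of the 19 measured members fell and 0 rose, or 14 and 1 adjusted over the list alone, with a list mean difference of -0.86. The type I interferon list had camera adjusted p = 5.94e-08, adjusted p = 0.207 with an estimated correlation and exact permutation adjusted p = 0.0261. Oas2, an antiviral oligoadenylate synthetase, fell by 2.42 ± 0.28 (adjusted p = 0.00222), the translation inhibitor gene Ifit1 fell by 1.75 ± 0.27 (adjusted p = 0.00688), and the antiviral gene Rsad2 fell by 1.68 ± 0.33 (adjusted p = 0.0179). Without inflamed replicate 3 the Rsad2 call ended (adjusted p = 0.0541), and the fallen members then numbered 8.

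**Figure D2:**
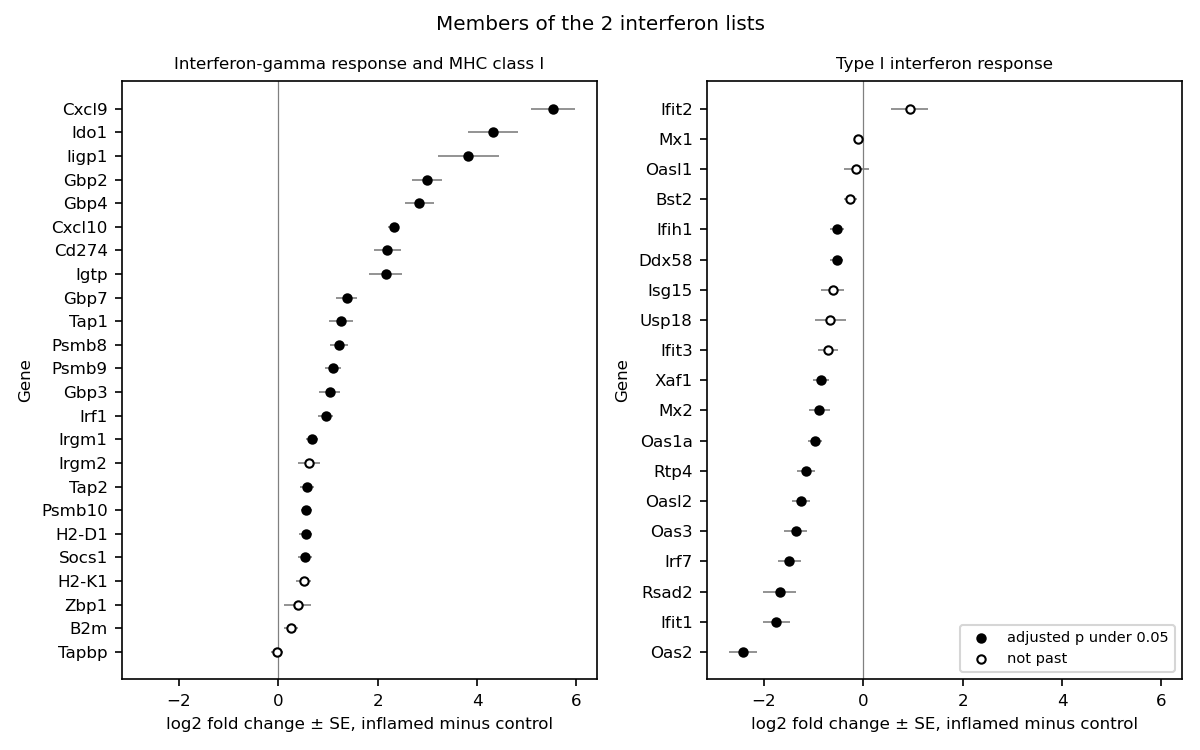
Points are the log2 fold changes (horizontal axis, inflamed minus control, with SE bars, n = 5 and 3) of the measured members of the interferon-gamma and MHC class I list (left) and the type I interferon list (right). Filled points passed the adjusted p threshold of 0.05: 19 of 24 on the left, all higher, and 12 of 19 on the right, all lower.

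MHC class II genes, which present antigen to CD4 T cells, were higher in inflamed colon but varied among controls. In that list 5 of the 9 measured members rose and 0 fell, or 7 and 0 adjusted over the list alone, with a mean 1.34 higher. The MHC class II list had camera adjusted p = 0.00017, adjusted p = 0.142 with an estimated correlation and exact permutation adjusted p = 0.0472. H2-DMb1, which helps load peptides, rose by 2.64 ± 0.65 (adjusted p = 0.0389), and the chains H2-Eb1 and H2-Aa rose by 2.21 ± 0.47 (adjusted p = 0.0224) and by 2.12 ± 0.55 (adjusted p = 0.0448). Control list means ranged from -0.46 to 0.75 around their own average, with controls 1 and 2 highest, against 1.29 to 1.43 on inflamed arrays. Without control 2, 3 or 5 or inflamed replicate 2, 3 members passed, and without control 4 or inflamed replicate 1 or 3 only 1. The H2-DMb1 and H2-Aa calls ended without any of those arrays and the H2-Eb1 call without control 4 or any 1 inflamed array (adjusted p = 0.0503 to 0.132). A floor on low values also ended the H2-DMb1 and H2-Aa calls.

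Cytokine, chemokine and complement genes were higher. Of the cytokines and their receptors, 7 of the 23 measured members rose and 0 fell, or 8 and 0 adjusted over the list alone. The cytokine list had camera adjusted p = 0.000184, adjusted p = 0.156 with an estimated correlation and exact permutation adjusted p = 0.0261. Il1b led, followed by Il1f9, which encodes interleukin-36 gamma, by 3.09 ± 0.12 (adjusted p = 5.53e-05), and Il1a by 2.95 ± 0.52 (adjusted p = 0.0111). Among chemokines 11 of the 25 measured members rose and 1 fell, or 13 and 2 adjusted over the list alone. The chemokine list had camera adjusted p = 1.01e-08, adjusted p = 0.0767 with an estimated correlation and exact permutation adjusted p = 0.0261. The B cell attractant gene Cxcl13 rose by 3.11 ± 0.26 (adjusted p = 0.000657), and the neutrophil attractants Cxcl5 and Cxcl2 rose by 2.58 ± 0.10 (adjusted p = 5.56e-05) and by 2.55 ± 0.34 (adjusted p = 0.00377). In the complement and coagulation list 15 of the 20 measured members rose and 0 fell, or 16 and 1 adjusted over the list alone, with a mean 0.79 higher. The complement list had camera adjusted p = 5.55e-12, adjusted p = 0.0326 with an estimated correlation and exact permutation adjusted p = 0.0261. Plaur, the urokinase receptor, rose by 1.90 ± 0.17 (adjusted p = 0.000897), C1s1, a protease of the classical complement pathway, rose by 1.77 ± 0.074 (adjusted p = 5.76e-05), and Plat, tissue plasminogen activator, rose by 1.496 ± 0.18 (adjusted p = 0.00256). Of pattern recognition and inflammasome genes, 12 of the 29 measured members rose and 2 fell, or 18 and 2 adjusted over the list alone. The pattern recognition list had camera adjusted p = 7.27e-06, adjusted p = 0.142 with an estimated correlation and exact permutation adjusted p = 0.0261. The RNA sensor Tlr13 rose by 1.38 ± 0.14 (adjusted p = 0.00146) and Tnfaip3, an inhibitor of NF-κB signalling, rose by 1.28 ± 0.16 (adjusted p = 0.00275), whereas Tlr5, the flagellin receptor, fell by 1.18 ± 0.18 (adjusted p = 0.00622).

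Some genes of an antimicrobial and stress list rose, while some genes typical of several differentiated epithelial cell types fell. Of the antimicrobial and stress list, 10 of the 24 measured members rose and 2 fell, or 12 and 6 adjusted over the list alone. The antimicrobial list had camera adjusted p = 0.0112, adjusted p = 0.311 with an estimated correlation and exact permutation adjusted p = 0.0261. Beside Nos2, which is also on the macrophage list, the phospholipase gene Pla2g2a rose by 3.07 ± 0.45 (adjusted p = 0.00561) and Nox1, a superoxide-producing oxidase, rose by 2.55 ± 0.42 (adjusted p = 0.00836). Among genes of absorptive enterocytes and ion transport 10 of the 27 measured members fell and 2 rose, or 12 and 2 adjusted over the list alone, with a list mean difference of -0.41. The absorptive list had camera adjusted p = 0.000972, adjusted p = 0.229 with an estimated correlation and exact permutation adjusted p = 0.0472. The water channel Aqp8 fell by 2.15 ± 0.41 (adjusted p = 0.0151), the bile acid transporter subunit Slc51a fell by 1.503 ± 0.23 (adjusted p = 0.00597) and the chloride-bicarbonate exchanger Slc26a3 fell by 1.30 ± 0.32 (adjusted p = 0.0388). Camera no longer called the antimicrobial list without inflamed replicate 2 (adjusted p = 0.233) or with array weights (adjusted p = 0.13), and the absorptive mean was -0.26 without inflamed replicate 3. The Slc26a3 call ended without control 2, 3, 4 or 5 or inflamed replicate 1 or 3 (adjusted p = 0.0725 to 0.134), with a floor on low values and with sex as a block.

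Enteroendocrine and tuft cell genes were lower. Of the enteroendocrine list, 7 of the 17 measured members fell and 0 rose, or 11 and 0 adjusted over the list alone, with a mean difference of -0.79. The enteroendocrine list had camera adjusted p = 3.61e-06, adjusted p = 0.0976 with an estimated correlation and exact permutation adjusted p = 0.0261. The granins Chga and Chgb fell by 2.03 ± 0.22 (adjusted p = 0.00179) and by 1.71 ± 0.34 (adjusted p = 0.0179), and the proglucagon gene Gcg fell by 1.32 ± 0.34 (adjusted p = 0.0444). Of the tuft cell list, 7 of the 14 measured members fell and 0 rose, or 9 and 1 adjusted over the list alone. The tuft cell list had camera adjusted p = 4.81e-05, adjusted p = 0.0976 with an estimated correlation and exact permutation adjusted p = 0.0261. Rgs13, a regulator of G-protein signalling, fell by 1.52 ± 0.27 (adjusted p = 0.012), the taste G-protein gene Gnat3 fell by 0.89 ± 0.17 (adjusted p = 0.0154) and the adaptor gene Sh2d6 fell by 0.67 ± 0.10 (adjusted p = 0.00565). Without inflamed replicate 1, 3 enteroendocrine and 3 tuft genes passed, and without control 5, 4 enteroendocrine genes. The Chgb, Rgs13 and Gnat3 calls ended without inflamed replicate 1 (adjusted p = 0.0707, 0.052 and 0.0612), and the Gcg call without any 1 control or inflamed replicate 1 or 3 (adjusted p = 0.0722 to 0.15), with a floor on low values or with sex as a block.

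Goblet cell genes were lower on inflamed replicates 1 and 3 but not on replicate 2, with list means of -0.49, -0.30 and 0.0723 on replicates 1, 3 and 2. In that list 8 of the 19 measured members fell and 0 rose, or 9 and 2 adjusted over the list alone. The goblet cell list had camera adjusted p = 0.00474, adjusted p = 0.363 with an estimated correlation and exact permutation adjusted p = 0.151. Creb3l1, a secretory transcription factor, fell by 1.16 ± 0.28 (adjusted p = 0.0364), Gcnt3, which branches mucin glycans, fell by 1.09 ± 0.13 (adjusted p = 0.00232), and Atoh1, which specifies secretory cells, fell by 1.09 ± 0.15 (adjusted p = 0.00439). The list mean difference of -0.24 was -0.115 without inflamed replicate 1 and -0.40 without replicate 2. With sex as a block 5 members fell. Without any 1 control or inflamed replicate 3, 4 members passed, without inflamed replicate 1, 3 did, and without any of these arrays, or with a floor on low values, the Creb3l1 call ended (adjusted p = 0.0632 to 0.109).

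Crypt and adhesion genes passed no list test, and members moved both ways. Of the crypt stem cell and Wnt target list, 4 of the 18 measured members fell and 3 rose, or 6 and 4 adjusted over the list alone. The crypt list had camera adjusted p = 0.199, adjusted p = 0.4 with an estimated correlation and exact permutation adjusted p = 0.167. Cd44 and Myc, Wnt targets, rose by 0.77 ± 0.14 (adjusted p = 0.0123) and by 0.52 ± 0.10 (adjusted p = 0.0161), and Lgr5, the stem cell marker, fell by 0.57 ± 0.15 (adjusted p = 0.0443). Of tight junction and adhesion genes, 3 of the 22 measured members rose and 1 fell, or 3 and 1 adjusted over the list alone. The adhesion list had camera adjusted p = 0.669, adjusted p = 0.79 with an estimated correlation and exact permutation adjusted p = 0.231. The claudin genes Cldn4 and Cldn15 moved apart: Cldn4 rose by 1.77 ± 0.22 (adjusted p = 0.00313) and Cldn15 fell by 0.86 ± 0.18 (adjusted p = 0.0214), while the desmosomal gene Pkp2 rose by 0.69 ± 0.15 (adjusted p = 0.0227). Without control 1, 2, 3 or 4 or inflamed replicate 1, 2 crypt genes fell and without inflamed replicate 3, 1 did, and the Lgr5 call ended without any 1 control or inflamed replicate 1 or 3 (adjusted p = 0.0817 to 0.149), with a floor, with sex as a block, and under quantile or median scaling. The Cldn15 call ended without control 2 or 3 or inflamed replicate 1 or 3 (adjusted p = 0.0511 to 0.0817) and that of Pkp2 without control 2 or 5 or inflamed replicate 1 (adjusted p = 0.0502 to 0.053).

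Most genes of a detoxification list fell, and so did some genes of fatty acid oxidation. Of the xenobiotic and steroid metabolism list, 24 of the 34 measured members fell and 1 rose, or 26 and 1 adjusted over the list alone, with a list mean difference of -1.33. The xenobiotic list had camera adjusted p = 9.43e-13, adjusted p = 0.122 with an estimated correlation and exact permutation adjusted p = 0.0261. Beside the sulfotransferases, the cytochrome P450 gene Cyp2c55 fell by 2.99 ± 0.73 (adjusted p = 0.0385). The list means were -1.44, -0.84 and -1.70 on inflamed replicates 1, 2 and 3. Of the fatty acid oxidation and ketogenesis list, 10 of the 23 measured members fell and 1 rose, or 14 and 1 adjusted over the list alone. The fatty acid list had camera adjusted p = 3.21e-06, adjusted p = 0.192 with an estimated correlation and exact permutation adjusted p = 0.0261. Ppargc1a, a coactivator of mitochondrial genes, fell by 1.97 ± 0.37 (adjusted p = 0.0152), the lipid sensor Ppara fell by 1.42 ± 0.11 (adjusted p = 0.000504) and the dehydrogenase Hadh fell by 1.03 ± 0.17 (adjusted p = 0.00934). Cyp2c55 changed by -1.95 without inflamed replicate 3, and its call ended without any 1 control or inflamed replicate 1 (adjusted p = 0.0751 to 0.0916) or with a floor on low values. Without inflamed replicate 1, 6 fatty acid genes passed and the Ppargc1a call ended (adjusted p = 0.0611).

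In the glycolysis and hypoxia list 13 of the 21 measured members rose and 0 fell, or 17 and 0 adjusted over the list alone, with a mean 0.76 higher. The glycolysis list had camera adjusted p = 3.13e-11, adjusted p = 0.122 with an estimated correlation and exact permutation adjusted p = 0.0261. Pfkfb3, which stimulates glycolysis, rose by 1.93 ± 0.13 (adjusted p = 0.000315), Adm, the hypoxia-induced peptide adrenomedullin, rose by 1.78 ± 0.24 (adjusted p = 0.00447), and Hif1a, a hypoxia-inducible factor subunit, rose by 1.66 ± 0.21 (adjusted p = 0.00315). Of the oxidative phosphorylation and citric acid cycle genes, 1 of the 29 measured members fell and 0 rose, or 1 and 0 adjusted over the list alone. The oxidative phosphorylation list had camera adjusted p = 0.0183, adjusted p = 0.486 with an estimated correlation and exact permutation adjusted p = 0.231. Ogdh, a dehydrogenase of that cycle, fell by 0.45 ± 0.063 (adjusted p = 0.00479), and Sdhb differed by -0.29 ± 0.079 (adjusted p = 0.0512). Without inflamed replicate 1 the fallen genes numbered 2 and without replicate 2 they numbered 6, while camera no longer called the list without inflamed replicate 3 (adjusted p = 0.382) or control 3 (adjusted p = 0.0667). Its list mean difference of -0.094 was -0.0505 without inflamed replicate 3.

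Proliferation and protein-folding genes were higher. Of the cell cycle list, 14 of the 23 measured members rose and 0 fell, or 22 and 0 adjusted over the list alone, with a mean 0.56 higher. The cell cycle list had camera adjusted p = 5.21e-12, adjusted p = 0.155 with an estimated correlation and exact permutation adjusted p = 0.0261. The ribonucleotide reductase gene Rrm2 rose by 1.29 ± 0.17 (adjusted p = 0.00333), the topoisomerase gene Top2a rose by 0.92 ± 0.14 (adjusted p = 0.00715) and the replication licensing gene Mcm3 rose by 0.83 ± 0.19 (adjusted p = 0.0309). In the unfolded protein response list 7 of the 18 measured members rose and 2 fell, or 10 and 2 adjusted over the list alone. The unfolded protein list had camera adjusted p = 0.00273, adjusted p = 0.217 with an estimated correlation and exact permutation adjusted p = 0.0261. Atf3, a stress transcription factor, rose by 0.75 ± 0.12 (adjusted p = 0.00939), the chaperone Hspa5 rose by 0.71 ± 0.14 (adjusted p = 0.0157), and Ern2, the stress sensor of mucus-producing cells, fell by 0.94 ± 0.16 (adjusted p = 0.0104). Without control 3 or 4 or inflamed replicate 3, 9 cell cycle genes passed, without inflamed replicate 1, 7, and without control 4, 4 unfolded protein response genes. The Mcm3 call ended without control 3 or 4 or any 1 inflamed array (adjusted p = 0.0694 to 0.0912) or with a floor on low values, and the Hspa5 call without inflamed replicate 1 (adjusted p = 0.0502).

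The matrix protease genes Mmp7, Mmp10 and Mmp13 rose and most genes of a smooth muscle list fell. Of the extracellular matrix and protease list, 9 of the 27 measured members rose and 1 fell, or 13 and 1 adjusted over the list alone, with a mean 0.67 higher. The matrix list had camera adjusted p = 1.08e-07, adjusted p = 0.192 with an estimated correlation and exact permutation adjusted p = 0.0261. Matrilysin (Mmp7) rose by 3.59 ± 0.28 (adjusted p = 0.000543), Mmp10, a stromelysin, rose by 2.64 ± 0.40 (adjusted p = 0.00603), and Mmp13, a collagenase, rose by 2.30 ± 0.54 (adjusted p = 0.0338). Of the smooth muscle list, 10 of the 16 measured members fell and 0 rose, or 15 and 0 adjusted over the list alone, with a mean difference of -0.60. The smooth muscle list had camera adjusted p = 1.55e-08, adjusted p = 0.188 with an estimated correlation and exact permutation adjusted p = 0.0261. Pcp4, a calmodulin regulator, fell by 1.41 ± 0.36 (adjusted p = 0.045), calponin (Cnn1) fell by 0.77 ± 0.14 (adjusted p = 0.0112) and desmin (Des) fell by 0.73 ± 0.17 (adjusted p = 0.0298). With sex as a block 15 matrix genes rose, and without inflamed replicate 2 or 3, 6 muscle genes fell. The Mmp13 call ended without any 1 control or inflamed replicate 2, the Pcp4 call without any 1 control or inflamed replicate 2 or 3, and the Des call without control 2 or 5 or any 1 inflamed array (adjusted p = 0.0572 to 0.102). A floor also ended the Mmp13 and Pcp4 calls, array weights that of Pcp4 and sex as a block those of Pcp4 and Des.

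Fibroblast genes passed no list test, and 3 of the 20 measured members rose and 2 fell, or 4 and 2 adjusted over the list alone. The fibroblast list had camera adjusted p = 0.677, adjusted p = 0.841 with an estimated correlation and exact permutation adjusted p = 0.432. The median change was -0.0311, while the mean was 0.0613 and camera's direction upward. Thy1, also a T cell marker, and S100a4, also expressed by leukocytes, rose by 0.58 ± 0.081 (adjusted p = 0.00471) and by 0.53 ± 0.072 (adjusted p = 0.00439), and Dpt, a matrix protein gene, fell by 0.58 ± 0.15 (adjusted p = 0.0422). The Dpt call ended without control 1, 3, 4 or 5 or any 1 inflamed array (adjusted p = 0.0515 to 0.111), with a floor, array weights or sex as a block, and the fibroblast mean was 0.105 without inflamed replicate 2 and -0.00707 without replicate 3.

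Of the list of enteric neurons and glia, 4 of the 20 measured members fell and 0 rose, or 6 and 1 adjusted over the list alone. The neuronal list had camera adjusted p = 0.00221, adjusted p = 0.207 with an estimated correlation and exact permutation adjusted p = 0.0472. Snap25, of the synaptic release machinery, fell by 0.96 ± 0.21 (adjusted p = 0.0255), the neuropeptide gene Gal fell by 0.70 ± 0.10 (adjusted p = 0.00444) and Stmn2, a neuronal stathmin, fell by 0.62 ± 0.16 (adjusted p = 0.0437). In the list of endothelium and leukocyte adhesion 6 of the 24 measured members rose and 0 fell, or 8 and 1 adjusted over the list alone. The endothelial list had camera adjusted p = 0.000172, adjusted p = 0.0976 with an estimated correlation and exact permutation adjusted p = 0.0261. It was led by Itgb2 and Itgal, integrin chains that leukocytes carry, by 2.17 ± 0.085 (adjusted p = 5.53e-05) and by 1.72 ± 0.12 (adjusted p = 0.000414), and by Vcam1, their endothelial counterpart for other integrins, by 1.52 ± 0.093 (adjusted p = 0.000237). Without control 2 or 4, 1 neuronal gene passed, and without control 5 or inflamed replicate 1 or 2, or with sex as a block, 2 did. The Snap25 call ended without control 2 or 4 or inflamed replicate 1 or 3 (adjusted p = 0.0527 to 0.0944) and that of Stmn2 without any 1 control or inflamed replicate 1 or 2 (adjusted p = 0.0536 to 0.0967), with a floor or with sex as a block.

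Of the p21-activated kinases themselves, Pak2, Pak3, Pak4, Pak6 and Pak7 did not differ detectably in transcript level, and Pak1 had no named probe set. Pak2 was at 9.75 ± 0.10 in controls (SD, n = 5) and 9.78 ± 0.08 in inflamed colon (SD, n = 3), with a 95% interval of the difference from -0.12 to 0.18 (adjusted p = 0.801). For Pak4 the difference was 0.00597, with an interval from -0.12 to 0.13, and for Pak6 it was 0.00626, from -0.12 to 0.13. Pak3 and Pak7 lay below the array median in both groups, with differences of -0.0105 and 0.00242. Many deposited values of these genes are identical between arrays. Pak4 was at 8.4155 on control 1 and inflamed replicates 1, 2 and 3, and Pak2 at 9.7338 on control 5 and inflamed replicates 1 and 3. Pak3 and Pak7 each held a single value on most arrays. The small differences and their intervals rest in part on these ties and are uncertain. With 1 array left out the difference ranged from -0.0175 to 0.0549 for Pak2, from -0.0175 to 0.0392 for Pak4 and from -0.0474 to 0.0739 for Pak6, so none had a settled sign. Of the list of these kinases and their partners, 6 of the 28 measured members rose and 1 fell, or 7 and 1 adjusted over the list alone. The kinase list had camera adjusted p = 0.00132, adjusted p = 0.099 with an estimated correlation and exact permutation adjusted p = 0.0261. The leading risers were activators and GTPases of the Rac pathway that are found in blood cells: Dock2 rose by 1.80 ± 0.17 (adjusted p = 0.00106), Rac2 rose by 1.32 ± 0.13 (adjusted p = 0.00119) and Vav1 rose by 0.82 ± 0.085 (adjusted p = 0.0015). Transcript levels say nothing of kinase activity.

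The Hox, fat, ribosomal, red blood cell and sex-linked lists, fixed as checks of sampling, passed no list test, which does not show that sampling was equal. The clock list was fixed as a check too, and it did pass (camera adjusted p = 0.00109, exact permutation adjusted p = 0.0261). The sex-linked list joins Xist with Y-linked genes, which move oppositely, so its mean cannot show a difference in sex. Of distal hindgut Hox genes and Prac1, which mark the position along the colon, 0 of 9 passed (0 adjusted over the list alone), with a mean difference of 0.10. The Hox list had camera adjusted p = 0.991, adjusted p = 0.995 with an estimated correlation and exact permutation adjusted p = 0.679. Hoxd13 differed by 1.38 ± 0.91 (adjusted p = 0.357) and Hoxb13 by -0.45 ± 0.39 (adjusted p = 0.479). Without inflamed replicate 2 these differences were 0.81 and -0.72, and without replicate 3 they were 2.28 and -0.12. Hoxd13 ranged from 4.53 to 7.59 over controls and from 5.25 to 8.17 over inflamed arrays, so it varied widely within both groups. The median of that list was -0.0379 and camera's direction was downward, against a positive mean, which was 0.0119 without control 1 and 0.187 without control 5, and 0.0231, -0.00936 and 0.278 without inflamed replicates 1, 2 and 3. Of fat and mesothelium genes, 1 of 13 fell (0 adjusted over the list alone, camera adjusted p = 0.217, adjusted p = 0.486 with an estimated correlation, exact permutation adjusted p = 0.0686). The lipase gene Pnpla2 fell by 0.48 ± 0.13 (adjusted p = 0.0499), and Cidec, a lipid droplet gene, differed by -0.30 ± 0.12 (adjusted p = 0.143). The Pnpla2 call ended without any 1 control or inflamed replicate 1 or 3 (adjusted p = 0.0545 to 0.161), with a floor and under shifted scaling, and the count was 0 without control 1, 3, 4 or 5 or inflamed replicate 1.

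Of ribosomal protein genes 1 of the 14 measured members rose and 0 fell, or 1 and 0 adjusted over the list alone. The ribosomal list had camera adjusted p = 0.114, adjusted p = 0.523 with an estimated correlation and exact permutation adjusted p = 0.203. Rps9 rose by 0.37 ± 0.064 (adjusted p = 0.0112), and Rps20 differed by 0.20 ± 0.079 (adjusted p = 0.148). The list mean difference of 0.0598 was 0.0272 without inflamed replicate 1 and 0.0965 without replicate 2, and camera called the list without inflamed replicate 2 (adjusted p = 0.0361), without control 3 (adjusted p = 0.044) or with array weights (adjusted p = 0.0321). Only 3 red blood cell genes were measured, none past the threshold, with Slc4a1 at -0.05 ± 0.031 (adjusted p = 0.326) and Alas2 at -0.05 ± 0.04 (adjusted p = 0.447) (list mean, exact permutation adjusted p = 0.151). Of 4 measured sex-linked genes 0 passed, with Xist at -2.09 ± 2.43 (adjusted p = 0.599) and Eif2s3y at 1.25 ± 1.31 (adjusted p = 0.561) (list mean, exact permutation adjusted p = 0.586). Leaving out inflamed replicates 1, 2 and 3 in turn gave -1.14, -0.93 and -4.20 for Xist and 0.68, 0.57 and 2.49 for Eif2s3y. Slc4a1 was at -0.0274 without inflamed replicate 2, and Alas2 at -0.0249 without control 2 and -0.0217 without inflamed replicate 1.

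Clock genes were lower. Of the clock list, 6 of the 16 measured members fell and 0 rose, or 8 and 2 adjusted over the list alone, with a mean difference of -0.45. The clock list had camera adjusted p = 0.00109, adjusted p = 0.192 with an estimated correlation and exact permutation adjusted p = 0.0261. The repressor gene Nr1d1 fell by 1.75 ± 0.14 (adjusted p = 0.000559), its co-cycling output gene Dbp fell by 1.72 ± 0.25 (adjusted p = 0.00555) and Per3, a period gene, fell by 0.80 ± 0.19 (adjusted p = 0.0361). Without control 1 or 4 or inflamed replicate 2 or 3, 3 clock genes passed, and the Per3 call ended without control 1, 3 or 4 or any 1 inflamed array (adjusted p = 0.0555 to 0.102), with a floor or with sex as a block.

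**Figure D3:**
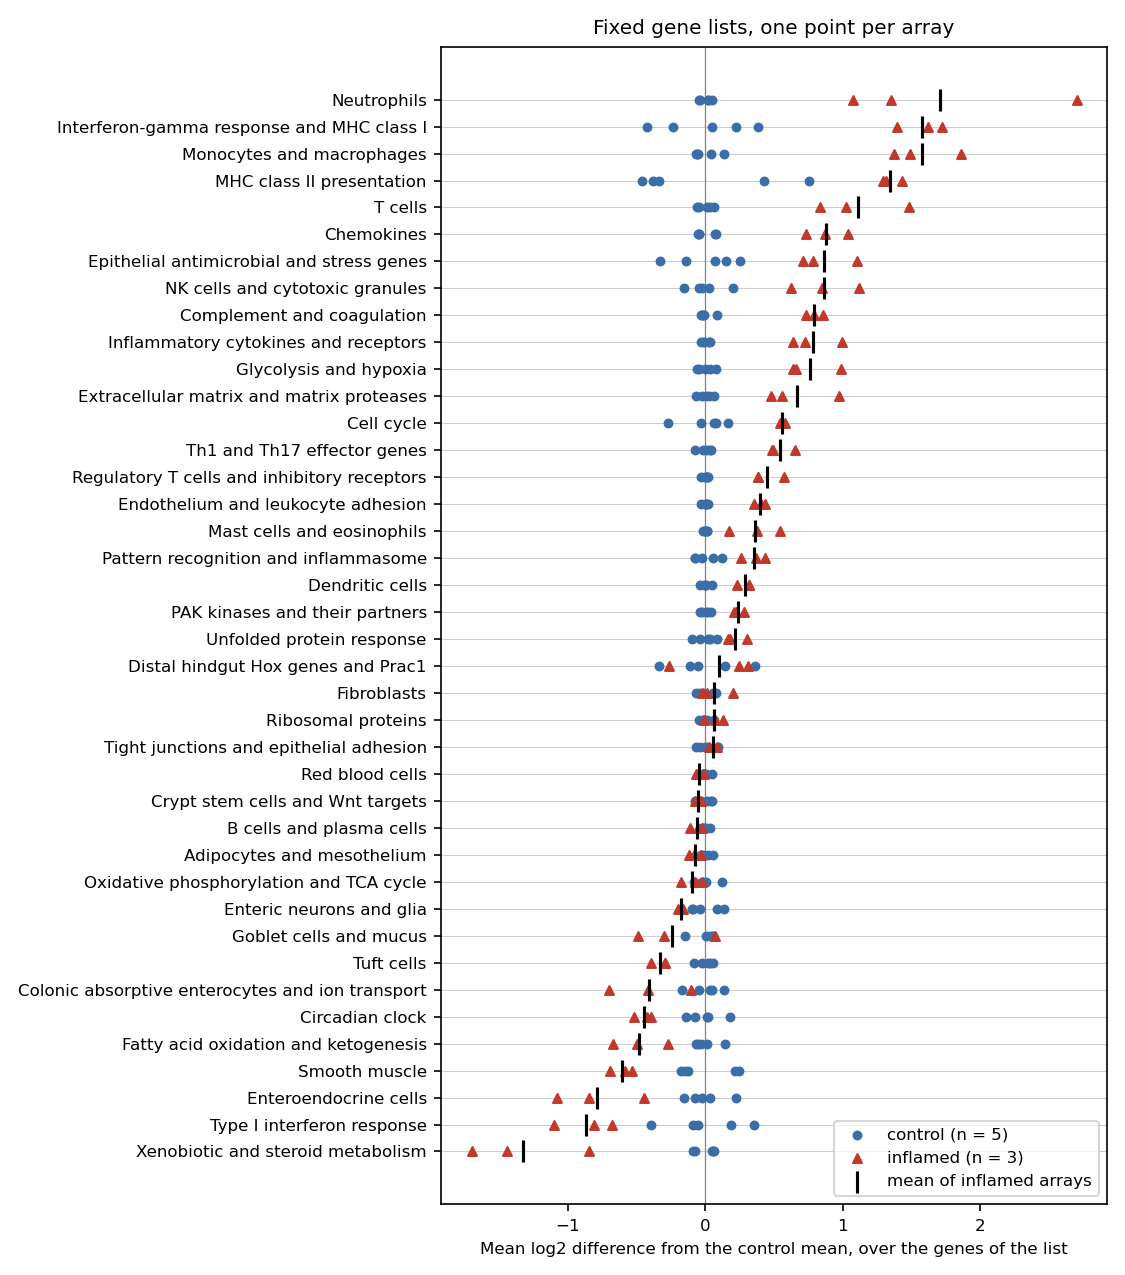
Each point is the mean over a list's measured genes on 1 array, as the log2 difference from the average of the 5 controls (horizontal axis); circles are control and triangles inflamed arrays, and the black bar is the mean of the 3 inflamed arrays. By the mean of the 3 inflamed arrays, the neutrophil list lies highest (1.71) and the xenobiotic list lowest (-1.33). On inflamed replicates 1 and 2 the neutrophil list (1.07 and 1.35) lies under the interferon-gamma list (1.72 and 1.39). The mean of the type I interferon list lies below the controls (-0.86) while that of the interferon-gamma list lies above them (1.58).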

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

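The tests of explanations in this part were all chosen after the results they address had been seen. A control whose gap from the other 4 exceeded 0.71 of the control range was found for 13 of 175 values tested, where chance gives about 5%. The values are log2 levels of that control, and list means are log2 differences from the control average. The rule ignores size. Pak3 counts although control 5 differed by only 0.0366 from the others, which were identical, and Alas2 held tied values too.

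Mptx1 was at 8.3605 on control 1, against 11.57 to 12.22 on the other controls, and Mptx2 was at 7.4565 there, against 10.26 to 11.05. Control 1 also had a list mean of 0.0818 for complement and coagulation, against -0.0293 to -0.00847 on the others, and 5.9518 for Pak6. On control 5, Capg was at 6.9764, Vav1 at 5.9418, Pak3 at 4.7928, and the goblet cell list mean at -0.146. Il1f9 was at 4.231 on control 4. On control 3, Lgr5 was at 6.1518, Sdhb at 9.4966 and Rps9 at 7.4299. Alas2 was at 5.081 on control 2. Outside the named genes, 1444 of 33206 transcript clusters without a gene symbol also changed, 685 higher and 759 lower.

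The fall of type I interferon genes beside the rise of interferon-gamma genes was weighed against several technical readings. An even loss of all epithelial RNA would lower the adhesion list about as much as the type I list. The adhesion list had a median change of 0.00809 and a lower quartile of -0.151, above the median of the type I list (-0.845). It is not a neutral gauge, since 3 of its 22 measured members rose and 1 fell. A loss offset by such rises is therefore not excluded. Other scalings left the median of the type I list at -0.808 or lower. Leaving out any 1 control left at least 9 fallen members. Loss of mature epithelial cells alone may still contribute, since the xenobiotic (-1.37), enteroendocrine (-0.53) and absorptive (-0.293) list medians were lower too, and no cause is assigned.

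The lower clock genes may reflect mice killed at another time of day or inflammation itself. A shifted phase would raise genes that peak opposite to Dbp, and these 5 (Arntl, Clock, Npas2, Cry1 and Nfil3) had a median change of 0.034 with 0 past the threshold (the values were -0.05, 0.03, -0.25, 0.22 and 0.51), so the time of death cannot be told apart from other causes without recorded times. The unequal sexes are a poor explanation, as the median of the list was -0.358 with sex as a block.

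Inflamed replicate 2 stood apart from the other inflamed arrays, with a smaller fall of xenobiotic genes and a goblet cell list mean (0.0723) above every control. Its separation of exonic from intronic control probe sets was the lowest of the 8 arrays (0.8775, against 0.8829 to 0.8984), but by less than the range of the others, so a difference in array or RNA quality cannot be told apart from a milder or different disease. Sex is a poor explanation, since it correlated at 0.987 with inflamed replicate 1, of its own pattern, whereas replicates 1 and 3, of different patterns, correlated at 0.995.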

How the results depend on the processing

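A block for sex, leaving out genes with under 5 distinct values, and the exact permutation of list means were chosen after the data were seen, as were the tests against other splits. In 1 of the 56 splits of the arrays into 5 and 3, the real one, as many as 4025 genes changed (highest other 0), and likewise for the 730 genes changed at least 2-fold (highest other 0), so a chance assignment of arrays to groups does not give those counts. For the 31 lists called by camera, 3 splits gave as many, the highest other 33 (controls 1, 3 and 5 set against the rest), so this comparison does not exclude chance for that count, although that split still parts 3 controls from all inflamed arrays and so holds some of the real difference. The exact test also called 31 lists, but not the same ones: the goblet cell and oxidative phosphorylation lists dropped out, and the B cell and mast cell lists came in. It does not grade lists, since the B cell list (-0.0629) had the same adjusted p of 0.0261 as the macrophage list (1.57). That value also depends on 28 lists sharing the smallest p. No lists of random genes were run through it, so a call there does not set a list apart from other genes. Gene-level alternatives were other scalings, a floor on low values, dim genes left out, probe set means and an intensity trend. Others were array weights, sex as a block and tied genes left out. Over these, 3235 to 5681 genes changed, 663 to 819 changed at least 2-fold, and camera called 30 to 33 lists. With every probe set tested, 4964 of 65956 transcript clusters changed, 1048 of them at least 2-fold. Shifting arrays to a common median made 71.1% of changed genes higher, against 61.5%. At a threshold of 0.01, 1584 genes changed, as the stricter level itself implies. Leaving out 1 array gave 2507 to 4566 genes, 618 to 827 at least 2-fold and 31 or 32 lists, the lowest without inflamed replicate 1. Camera with an estimated correlation called 1 list and fry 32; estimating the correlation widens the null for lists whose genes move together. Over the settings other than the list tests just named, calls of named genes were kept 1898 times and lost 280 times, and those of lists kept 584 times and lost 5 times; genes and lists not called gained a call 7 and 15 times. No direction of a called gene or list turned. No pairing by replicate number was seen: deviations of same-numbered arrays correlated at -0.285, -0.0525 and 0.0688, against -0.218 to 0.346 for differently numbered ones. So few pairs cannot exclude a shared batch or litter. With the replicate number as a block, limma called 0 genes and 0 genes changed at least 2-fold, with 4913 at an unadjusted p under 0.05, and camera called 31 lists; that fit leaves 2 residual degrees of freedom. Low signal limits the dimmer genes, where 196 of 11075 changed, and 188 changed genes had 1 group mean under the dim limit of 4.88, so that their folds are understated.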

Other observations

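The tests in this part were all chosen after the data were seen. Gene families grouped by symbol, some with members on the fixed lists, also moved together. Genes with the symbol roots of proteasome subunits rose, among them Psma5 by 0.66 ± 0.062 (adjusted p = 0.00113) and Psmd14 by 0.78 ± 0.071 (adjusted p = 0.001): 7 of 9 Psma, 7 of 12 Psmb, 6 of 7 Psmc and 8 of 14 Psmd genes changed, all higher (one-sided Fisher's exact adjusted p = 0.000221, 0.00154, 0.000451 and 0.000703), the pseudogenes Psma5-ps and Psmb5-ps among them. Of the Gimap family of lymphocyte GTPases 5 of 8 rose (adjusted p = 0.0109), of the guanylate-binding proteins 7 of 7 (adjusted p = 1.31e-05), of the annexins 6 of 11 (adjusted p = 0.00735) and of the calcium-activated chloride channel regulators (Clca) 6 of 8 (adjusted p = 0.000873), although the goblet cell product Clca1 fell by 0.96 ± 0.18 (adjusted p = 0.013). Slc7a11, the cystine importer that feeds glutathione synthesis, was 1 of 20 genes with the root Slc that rose, by 3.27 ± 0.14 (adjusted p = 7.24e-05).

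Downward, 12 of 19 carboxylesterases (Ces, adjusted p = 7.99e-08), 5 of 7 mu-class glutathione transferases (Gstm, adjusted p = 0.000998), 7 of 11 glucuronosyltransferases (Ugt, adjusted p = 0.00015) and 8 of 19 hydroxysteroid dehydrogenases (Hsd, adjusted p = 0.000703) fell, while 3 Hsd genes rose. Of 372 genes with the root Slc, mostly solute carriers, 52 fell (adjusted p = 1.49e-05) and 20 rose. The roots also take in other genes, such as Slc9a3r1, a scaffold protein gene, and pseudogenes. Of the tissue kallikreins 11 of 24 fell (adjusted p = 1.45e-05), led by Klk1b5 by 2.61 ± 0.48 (adjusted p = 0.014), and 6 of 10 oligoadenylate synthetases (adjusted p = 0.000703). Interferon-inducible genes with the root Ifi went mostly the other way, 8 of 14 higher (adjusted p = 0.000703) and 3 lower. Kallikreins, Hmgb1 pseudogenes (in the Hmgb family, 12 of 16 higher, adjusted p = 1.99e-07) and other near-identical copies may share probes and are uncertain as separate genes. In all, 38 of 512 families of at least 6 genes sharing a symbol root passed (26 higher, 12 lower, over 1024 tests), and none of these 38 family medians changed sign under 3 other scalings. Members of a family are not independent, so these p-values are too small.

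Among controls, MHC class II list means were 0.75 and 0.43 on controls 1 and 2, the arrays with Y-linked transcripts, and -0.34, -0.38 and -0.46 on controls 3, 4 and 5. The labels give no cause, and none was tested.

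Many deposited values are identical between arrays: only 12379 of 30671 genes (40.4%) had 8 distinct values, and 207 had the same value on all 8 arrays. Leaving out genes with under 5 distinct values gave 4603 changed genes of 26474 tested.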
